A study of Mus musculus with 14 samples.

How the data were processed

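Chromatin immunoprecipitation with sequencing (ChIP-seq) had been carried out on mouse cells that the labels name PDGF neural stem cells and that the series' design text calls mouse DIPG cells (diffuse intrinsic pontine glioma, a childhood brainstem tumour) expressing wild-type or K27M histone H3.3. The 14 samples comprised 8 H3K27me3 libraries, with 2 for each of the groups H3WT DMSO, K27M DMSO, H3WT EPZ and K27M EPZ, 1 Suz12 and 1 Ring1b library per genotype in DMSO, and 2 IgG libraries of H3WT DMSO cells. Peak lists of 12 libraries were analysed. The IgG libraries were not analysed here. Groups and replicate numbers were taken from the sample titles and descriptions. Per the labels' protocols, cells were treated with DMSO or with 3 µM EPZ6438 for 12 days, chromatin was crosslinked with formaldehyde and sonicated, and libraries were sequenced on an Illumina HiSeq2500.

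Bowtie 1.1.2 and the mouse build mm10 were named in the submitters' processing notes. The peak caller, its threshold, the control library it used and the number of reads per library were not given in the sources used here. One peak list was deposited per library, so replicates could be compared as separate lists. Each deposited list held the chromosome, start and end of every peak. The score column of the deposited lists was 0 in all 100144 lines, so no height, enrichment or p-value per peak was used. The narrowest deposited peak was 1001 bp wide, and every peak lay on chromosomes 1 to 19 or X. The 21 peaks that touched or overlapped a neighbour in the same library were merged with it. A peak list shows where the authors' caller passed its threshold and not how much of the mark was present. With unknown depth, a library with more reads or higher enrichment can yield more and wider peaks from the same chromatin, and no spike-in is named in the labels' protocols. Numbers of peaks and covered lengths therefore describe called regions. No counting interval based on reads could be given, and confidence intervals on shares are exact (Clopper-Pearson) 95% intervals that cover the counting of peaks or genes only.

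Covered length was the sum of merged peak widths. Gene positions came from a table of NCBI RefSeq genes of the assembly GRCm38.p6, whose chromosome sequences are those of mm10, and 21631 protein-coding genes on chromosomes 1 to 19 and X were used. The table holds no strand, so the transcription start planned as the centre of the promoter window was replaced, for every gene, by both gene ends: a gene was called marked where a peak overlapped the window of 1 kb to either side of its start or its end by at least 1 bp. A gene was H3WT-marked with such a peak in both H3WT DMSO libraries of H3K27me3. An H3WT-marked gene was retained with a peak in both K27M DMSO libraries, lost with a peak in neither, and partial with a peak in 1. A gained gene had peaks in both K27M DMSO libraries and in neither H3WT DMSO library. The value given for a named gene is its covered length, the length under peaks within 10 kb of either gene end, counted once where the windows meet. It cannot exceed the length of these windows, so a gene under peaks throughout has the same value in every library.

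Named genes followed a rule set before the data were examined. Cdkn2a, Cdkn2b, Ezh2, Suz12, Eed and Pdgfra were always included. Up to 10 retained, lost and gained genes, up to 10 genes with peaks in both EPZ libraries of a genotype, and up to 10 genes with Suz12 or Ring1b peaks in both genotypes or in 1 were taken by covered length, and up to 4 retained and 4 lost members came from each gene list. A few genes that this rule takes are not reported here. The 14 gene lists were fixed in advance. They held Hox clusters, other homeobox and paired-box factors, mesoderm and endoderm factors, neuronal differentiation, neural stem and glial progenitor genes, and astrocyte and oligodendrocyte differentiation. They also held cell cycle inhibitors and senescence, the Wnt, Bmp, Hedgehog, Fgf and TGF-beta signalling genes, Polycomb and H3K27 enzymes, imprinted genes, germline genes, mesenchymal, endothelial and microglial markers, PDGF and receptor tyrosine kinase signalling, and housekeeping genes. Of 536 list entries, 531 matched a gene by symbol, and the 5 that did not were the noncoding imprinted genes H19, Kcnq1ot1, Meg3, Rian and Airn.

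Per-library peak numbers and covered lengths were compared on the log2 scale with two-sided exact permutation tests over all relabellings. With 2 libraries against 2 the smallest possible p is 0.333, so a difference between genotypes within a treatment could not pass 0.05; with 4 against 4 it is 0.0286. Genotype and treatment were also tested together by permuting genotype labels within each treatment, over 36 relabellings. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Gene lists were compared with all other genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists tested, at an adjusted p of 0.05. For retention, only lists with at least 5 H3WT-marked members were tested, against all other H3WT-marked genes. Genes are not independent replicates, and neighbours share peaks. Peak overlap required 1 bp, and it was set beside the overlap after 1000 random placements of the K27M peaks on their own chromosomes. Peak widths were compared by a permutation test with 100000 resamples, in which peaks are not independent replicates. Suz12 and Ring1b had 1 library per genotype, so their values have no replicate check and no test.

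The alternatives were wider windows, a larger overlap with the window, marking in either replicate, each replicate left out, and merging of peaks within 3 kb. Further ones were removal of every peak that overlapped one of 117 regions with a peak in all 4 EPZ libraries, autosomes only, neighbouring genes counted as 1 locus, a larger peak overlap, the union of both K27M libraries, peak centres within 1 kb, and the replicate number as a block. The planned stricter threshold, peaks of at least 1 kb, removed 0 peaks and tested nothing, so peaks of at least 3 kb were added after the data had been seen. Retention against other marked genes with H3WT peaks at least as wide, tests of which list members kept a peak under EPZ, whole gene intervals as windows, and autosomes only for gene classes and peak overlap were also added then. A comparison of CpG content had been planned, and it was not run because it needs the genome sequence, which was not used here.

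The functions were tested on simulated data. In 200 simulated interval sets, 0 disagreed with a base-by-base count. In a simulation over 21631 genes, 100% of planted kept genes were recovered as retained and 99.25% of planted lost genes were not called retained. For gene lists, a list planted at 90% kept against 40% for other genes was called in 100% of 100 simulations, and unplanted lists were called in 0.843%. Each gene was drawn independently there, so these rates do not cover neighbours that share peaks. The width test on 2000 simulated peaks made calls in 4% of simulations with no difference and in 100% with a 2-fold difference. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.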

Results

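H3K27me3, the histone mark deposited by Polycomb repressive complex PRC2, was mapped by ChIP-seq in mouse PDGF neural stem cells expressing wild-type histone H3.3 (H3WT) or H3.3 with the K27M substitution, in which methionine replaces the lysine that carries the mark. Cells were treated for 12 days with DMSO, the solvent control, or with 3 µM EPZ6438 (EPZ), an inhibitor of Ezh2, the catalytic subunit of PRC2. Each of these 4 groups had 2 libraries. Suz12, another PRC2 subunit, and Ring1b (gene symbol Rnf2), the ubiquitin ligase of the complex PRC1, were mapped in DMSO with 1 library per genotype. The deposited data were peak lists of 12 libraries, with between 201 and 59899 peaks each, and the read depth of the libraries is unknown. Coordinates are those of mm10.

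In H3WT cells in DMSO, H3K27me3 lay over developmental regulators. Both libraries had a peak at an end of 37 of 39 Hox genes, which set position along the body axis, and of 65 of 78 other homeobox and paired-box genes. The mark was also at 35 of 47 mesoderm and endoderm factors, at 32 of 44 neuronal differentiation genes, and at 39 of 58 genes of Wnt, Bmp, Hedgehog, Fgf and TGF-beta signalling. Imprinted genes, which are expressed from one parental allele, carried it at 12 of 26. Among all 21631 protein-coding genes 2303 were marked, and 116 of these were on X. The other 8 lists were not separated from the remaining genes, of which 10.6 to 10.7% were marked. Among them were 2 of 34 neural stem and glial progenitor genes, 6 of 23 astrocyte and oligodendrocyte genes, 3 of 23 cell cycle inhibitors and 3 of 36 genes of Polycomb and H3K27 enzymes. The counts were 7 of 32 for germline genes, 2 of 32 for mesenchymal, endothelial and microglial markers, 5 of 25 for PDGF and receptor tyrosine kinase genes, and 0 of 34 for housekeeping genes. Fisher's exact test with Benjamini-Hochberg adjustment over 14 lists gave 3.28e-33 for Hox genes, 1.98e-49 for other homeobox genes and 3.69e-24 for mesoderm and endoderm factors. It gave 9.95e-22 for neuronal differentiation, 3.69e-24 for signalling and 1.11e-05 for imprinted genes. For the other lists the adjusted p ranged upward from 0.0595, that of the astrocyte and oligodendrocyte list. That list was called higher in 3 of 12 alternatives (lowest adjusted exact p = 0.0371). The germline list was called higher in 4, among them replicate 2 alone (18 of 32, adjusted exact p = 0.000109), and the PDGF and receptor tyrosine kinase list in 1, whole gene intervals (10 of 25, adjusted exact p = 0.00298). Housekeeping genes were called lower in 5 (lowest adjusted exact p = 0.000119, with neighbours as 1 locus), though not in the main comparison. Counting neighbouring genes as 1 locus ended the call for imprinted genes (Fisher's exact test, adjusted p = 0.363), which left the other 5 calls higher. In this setting a locus was marked if any of its genes was, and genes outside a list could chain into larger loci. That raises the marked share of the other loci, so a lower or ended call there can follow from locus size. Removing every peak that touched a region shared by all 4 EPZ libraries took away all peaks of the Hox genes (0 of 39 marked, adjusted exact p = 0.0588).

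**Figure D1:**
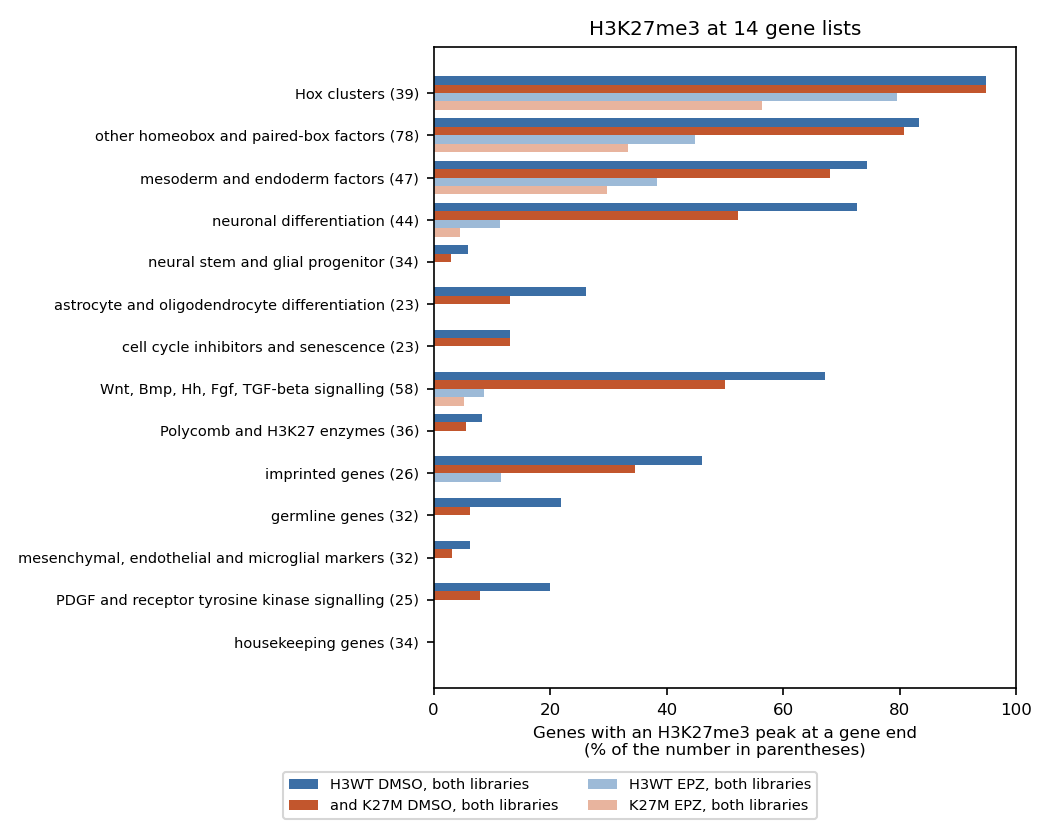
Share of the genes of each list (x axis, percent of the number in parentheses) with an H3K27me3 peak at a gene end in both libraries of H3WT DMSO (dark blue), in both libraries of H3WT DMSO and of K27M DMSO (dark orange), and in both EPZ libraries of H3WT (light blue) or K27M (light orange). The Hox clusters have 37, 37, 31 and 22 of 39 genes in these 4 sets, and the housekeeping genes have 0 in each.

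The comparison of K27M with H3WT in DMSO addressed how the mutant histone changes the distribution of the mark. Of the 2303 H3WT-marked genes, 956 were retained, with a peak in both K27M libraries (41.5%, exact 95% interval 39.5 to 43.6%). A further 429 were lost, with a peak in neither (18.6%, 17.1 to 20.3%), and 918 had a peak in K27M replicate 2 alone. As 0 had one in K27M replicate 1 alone, the retained class was set by replicate 1, the library with fewer peaks. Retained genes included Hoxb3 (chromosome 11, 96307101 to 96347930), with a covered length of 40 kb in each of the 4 libraries, and Gata2, a factor of blood development (chromosome 6, 88193891 to 88207032), with 29.7 ± 3.61 kb in H3WT and 28.2 ± 5.98 kb in K27M (SD, n = 2). Lost genes included Cbfa2t3, a transcriptional corepressor on chromosome 8 from 122625136 to 122699332 (28.1 ± 2.80 kb against 8.73 ± 8.44 kb, SD, n = 2), and Sycp1, a protein of the meiotic synaptonemal complex on chromosome 3 from 102818499 to 102936100 (20.9 ± 10.1 kb against 0.543 ± 0.768 kb). H3K27me3 peaks covered 130 ± 123 Mb in H3WT and 39.5 ± 36.8 Mb in K27M (SD, n = 2). The lengths were 43.6 and 217 Mb in the H3WT libraries of replicates 1 and 2 and 13.5 and 65.5 Mb in the K27M ones. Within a replicate number, the covered length in K27M was 3.24-fold (replicate 1) and 3.31-fold (replicate 2) lower, a mean log2 difference of -1.71. Peak number differed by a log2 value of -2.12, from 13358 and 59899 peaks in H3WT to 2351 and 17980 in K27M. Neither difference was larger than the spread between replicates (exact permutation test, p = 0.667 for both, where 0.333 is the smallest p that 2 against 2 allows). Replicate 2 covered 4.98-fold more than replicate 1 in H3WT and 4.87-fold more in K27M. The X chromosome held 10.0% and 30.9% of the covered length in the H3WT libraries and 3.54% and 36.4% in the K27M libraries.

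**Figure D2:**
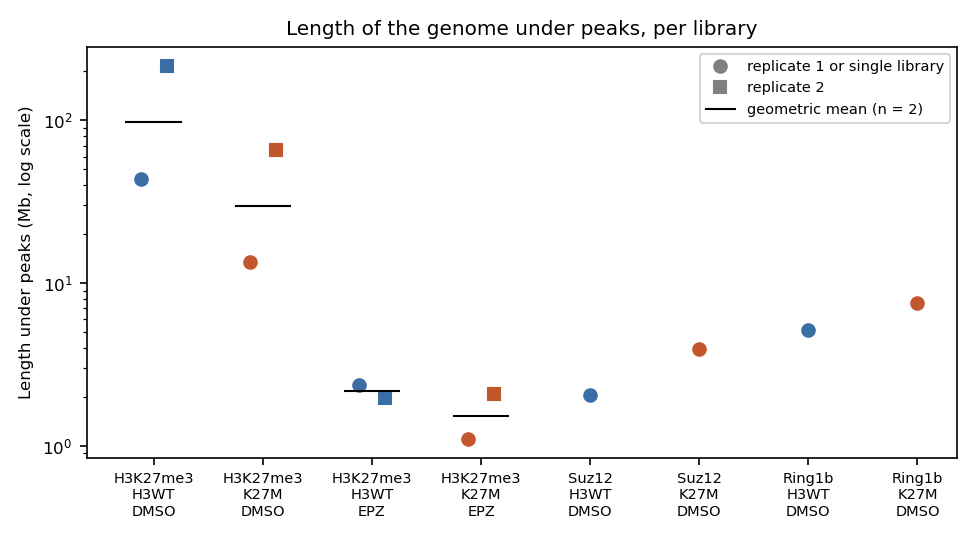
Length of the genome under peaks in each of the 12 libraries (y axis, Mb, log scale), with H3WT in blue and K27M in orange, replicate 1 or single libraries as circles, replicate 2 as squares and geometric means of 2 libraries as lines. The 4 H3K27me3 DMSO libraries range from 13.5 to 217 Mb and the 4 EPZ libraries from 1.1 to 2.36 Mb.

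Retention in K27M was not even across gene groups. All 37 marked Hox genes were retained, as were 63 of 65 other homeobox and paired-box genes, 32 of 35 mesoderm and endoderm factors, 29 of 39 signalling genes and 23 of 32 neuronal differentiation genes, against 40 to 41% of all other marked genes. Examples outside the Hox clusters were Pax9, a paired-box factor of tooth and thymus development (37.8 ± 2.79 kb in H3WT, 37.1 ± 1.52 kb in K27M, SD, n = 2), and Foxa1, a pioneer factor of endoderm (26.8 ± 0.267 kb, 26.9 ± 0.170 kb). Others were Neurog2, a proneural factor (21.2 ± 2.41 kb, 22.9 kb in both K27M libraries), and Wnt10a (30.7 ± 0.421 kb, 27.4 ± 3.13 kb). Fisher's exact test with Benjamini-Hochberg adjustment over the 9 lists with at least 5 marked members gave 2.21e-14 for Hox genes, 1.77e-21 for other homeobox genes and 1.94e-09 for mesoderm and endoderm factors. It gave 0.000103 for signalling and 0.00148 for neuronal differentiation. Imprinted genes were retained at 9 of 12 (adjusted exact p = 0.0522). They were called in 6 of 12 alternatives, with adjusted exact p from 0.00014, when marking in either replicate sufficed (13 of 13 retained), to 0.187. The retained ones included Magel2, Mkrn3, Kcnq1 and the growth factor gene Igf2, whose covered length was 21.3 ± 5.36 kb in H3WT and 15 ± 0.904 kb in K27M. No call was made for astrocyte and oligodendrocyte genes (3 of 6 retained, among them Slc1a2 and Nkx6-2), germline genes (2 of 7: Zpbp2 and Sycp2) or PDGF and receptor tyrosine kinase genes (2 of 5: Igf1r and Met). Too few marked genes for a test were in the lists of neural stem and glial progenitors (1 of 2 retained, Id4), cell cycle inhibitors (3 of 3), Polycomb and H3K27 enzymes (2 of 3, Pcgf1 and Cbx2), mesenchymal, endothelial and microglial markers (1 of 2, Flt1) and housekeeping genes. The call for neuronal differentiation ended with peaks of at least 3 kb (adjusted exact p = 0.0513), and Hox genes could not be tested without the peaks that touch regions shared by all EPZ libraries, since 0 of them were then marked. Between the H3WT libraries, 2303 of the 4955 genes marked in replicate 2 were also marked in replicate 1, which had fewer peaks. Whether the same lists stand out between these H3WT libraries was not tested. The list calls therefore do not separate genotype from a shorter peak list.

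Among the 429 lost genes, those with the widest H3WT cover after Cbfa2t3 were Gm884 (25.2 ± 13.0 kb in H3WT, 2.28 ± 3.23 kb in K27M, SD, n = 2), Jaml, a junctional adhesion molecule of leukocytes (24.6 ± 14.6 kb, 0.840 ± 1.19 kb), and Fsip2l on X (22.3 ± 17.0 kb, 4.52 ± 6.39 kb). The list of germline genes had 4 lost members. These were Sycp1, Dazl, an RNA-binding protein of germ cells (14.2 ± 1.60 kb, 1.21 ± 1.71 kb), Rhox13 (12.6 ± 9.08 kb, 0 kb) and Mov10l1, a helicase of the piRNA pathway (11.5 ± 6.90 kb, 4.93 ± 4.14 kb). Neuronal differentiation had 2, Calb2, which encodes calretinin (8.52 ± 5.77 kb, 0 kb), and Tubb3, a neuronal tubulin (2.54 ± 2.10 kb, 0 kb). Mobp, a myelin protein gene, and the ligand genes Bmp2 and Wnt2 were also lost. For most of these genes the H3WT libraries differed widely, and no gene was tested on its own, since 2 libraries against 2 cannot pass 0.05.

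Only 3 genes were gained, with peaks in both K27M libraries and in neither H3WT library at the gene ends. They included Gm46725 (chromosome 2, 18687502 to 18690731), with a covered length of 5.59 ± 3.34 kb in H3WT and 13.1 ± 4.20 kb in K27M (SD, n = 2). Prdm1, a transcriptional repressor of lymphoid and germ cell differentiation (chromosome 10, 44437174 to 44528558), had 0 kb and 5.20 ± 3.59 kb. The number of gained genes was 23 or 28 when 1 replicate was used alone and 1 with windows of 5 kb. That of lost genes was 1364 or 2586 with 1 replicate alone and 209 with peaks of at least 3 kb.

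Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 regulator Arf (chromosome 4, 89274473 to 89294619), was retained: its covered length was 26.2 ± 4.72 kb in H3WT and 30.0 ± 0.832 kb in K27M (SD, n = 2). In K27M the gene lay under a single peak of 29.5 kb in replicate 1 and of 30.9 kb in replicate 2. In H3WT a single peak of 29.9 kb lay over most of it in replicate 2, and peaks of 19.1 and 3.97 kb in replicate 1. Under EPZ Cdkn2a was listed at 0 kb in all 4 libraries. The neighbouring inhibitor gene Cdkn2b (chromosome 4, 89306289 to 89311032) was listed at 0 kb in all 12 libraries. The other marked cell cycle inhibitors were Cdkn1c, which is also imprinted (17.0 ± 7.84 kb, 9.36 ± 9.55 kb), and Gadd45b (4.76 ± 0.965 kb, 4.28 ± 2.07 kb). Genes of PRC2 itself, Ezh2, Suz12 and Eed, had no H3K27me3 peak within 10 kb of their ends in any library. Pdgfra, the receptor gene for PDGF (chromosome 5, 75151322 to 75198206), had 2.74 ± 1.77 kb in H3WT and 7.12 ± 3.56 kb in K27M, and both K27M libraries and H3WT replicate 2 had a peak at a gene end (3.99 kb covered in that H3WT library).

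**Figure D3:**
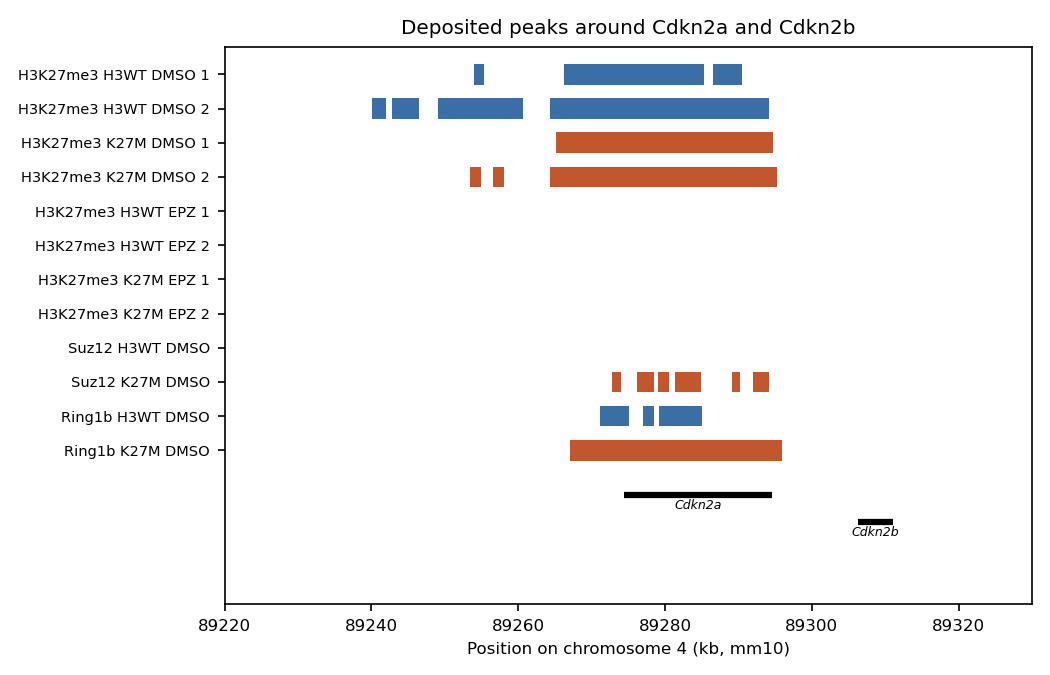
Deposited peaks of the 12 libraries (H3WT in blue, K27M in orange, 1 and 2 for replicates) around Cdkn2a and Cdkn2b, with position on chromosome 4 in kb on the x axis and genes as black bars. All 4 H3K27me3 DMSO libraries have peaks over Cdkn2a, the EPZ libraries have none in the region, and Suz12 has peaks there in K27M and none in H3WT.

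H3K27me3 peaks of H3WT cells that were overlapped by a K27M peak were wider than the others. Of the H3WT peaks, 14.3% in replicate 1 (1914 of 13358) and 20.4% in replicate 2 (12227 of 59899) were overlapped by a K27M peak of the same replicate number, against means of 0.860% and 9.86% for K27M peaks placed at random. The overlapped peaks had a median width of 6.44 kb in replicate 1 and 5.44 kb in replicate 2, and the others had 1.62 and 1.76 kb, 3.97-fold and 3.09-fold differences (permutation test, p = 1e-05 in both, the smallest that 100000 resamples can give). Wide peaks are also hit more often by chance, so overlap was set against random placement in quintiles of H3WT peak width. In the widest quintile, 54.5% and 60.2% of H3WT peaks were overlapped, against 1.51% and 19% at random. In the narrowest quintile, 1.12% were overlapped in replicate 1, within the highest random share of 1.20%, and 3.48% in replicate 2, below the random mean of 5.77%. In replicate 2, X held 16453 of the 59899 H3WT peaks and 8612 of the 17980 K27M peaks. Placement kept each peak on its chromosome, and the random shares given here include X. The dense X peaks therefore weigh on the comparison with random placement in replicate 2. Conversely, 95.4% and 95.5% of K27M peaks overlapped an H3WT peak of the same number, leaving 107 and 810 that did not. Across replicate numbers the share of H3WT peaks overlapped was 61.5% for replicate 1 against K27M replicate 2 and 2.55% for the opposite pair, and against the union of both K27M libraries the share over both replicates was 41.0%, where it was 17.4% within replicate numbers.

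**Figure D4:**
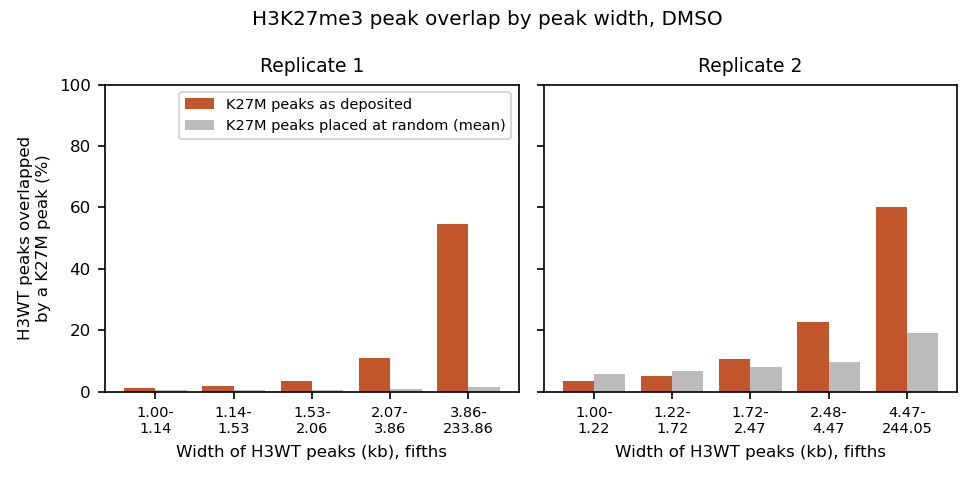
Share of H3WT H3K27me3 peaks overlapped by a K27M peak in DMSO (y axis, percent) by quintiles of H3WT peak width (x axis, kb) for replicates 1 and 2, with the deposited K27M peaks in orange and the mean of random placements in grey. The share is 54.5% and 60.2% in the widest quintile and 1.12% and 3.48% in the narrowest.

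Under EPZ, H3K27me3 peaks were called at part of the developmental regulators. In H3WT, 162 of the 2303 marked genes had a peak in both EPZ libraries (7.03%, exact 95% interval 6.02 to 8.16%), and in K27M 107 of 979 did (10.9%, 9.04 to 13.1%). All 4 EPZ libraries shared 104 genes, each of them also retained in K27M in DMSO. These held 22 Hox genes, 24 other homeobox and paired-box genes, 14 mesoderm and endoderm factors, 3 signalling genes and 2 neuronal differentiation genes. Hoxa11 had a covered length of 23.7 kb in every H3K27me3 library, with or without EPZ. Covered length is capped by its windows, so equal values do not show an unchanged amount of the mark. Hoxd10 had 30.8 kb in all DMSO libraries and between 26.1 and 30.8 kb under EPZ. In contrast, Hoxc4, with 38.8 kb in DMSO, had 30.6 and 26.1 kb in H3WT EPZ and 1.05 and 12.1 kb in K27M EPZ. Neurog2 and Wnt10a were listed at 0 kb in all 4 EPZ libraries. Pax9 was at 0 kb in 3 of them and had 6.93 kb, with a peak at a gene end, in K27M EPZ replicate 2.

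Covered length fell by 4.89 on the log2 scale with EPZ over both genotypes, 29.6-fold, to 2.17 ± 0.270 Mb in H3WT and 1.60 ± 0.698 Mb in K27M (SD, n = 2), and peak number fell by 5.66, 50.6-fold. All 4 EPZ libraries lay below all 4 DMSO libraries in both measures (exact permutation test, p = 0.0286 for each, the smallest that 4 against 4 allows). Libraries were relabelled without regard to genotype, and no joint test with relabelling within genotypes was run. Within H3WT the length was 18.5-fold and 110-fold lower in replicates 1 and 2, and within K27M 12.2-fold and 31.3-fold lower (exact p = 0.333 in each genotype, the smallest possible). The difference between genotypes in the EPZ effect, 1.20 on the log2 scale for length, was within the spread (exact permutation p = 0.611), and under EPZ the 2 genotypes differed by -0.51 (exact p = 0.667), with -1.10 in replicate 1 and 0.08 in replicate 2.

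Tests of the gene lists under EPZ were chosen after the data had been seen. In H3WT, 31 of 37 marked Hox genes had peaks in both EPZ libraries, as did 35 of 65 other homeobox and paired-box genes and 18 of 35 mesoderm and endoderm factors, such as Hand2, a factor of heart and limb development (23.5 kb in both H3WT EPZ libraries, 20.2 and 23.5 kb in K27M EPZ). In K27M the counts were 22 of 39, 26 of 63 and 14 of 33. These lists stood above the other marked genes (Fisher's exact test, adjusted p of 1.55e-30, 2.76e-24 and 3.40e-12 in H3WT and of 5.90e-12, 2.22e-10 and 4.25e-06 in K27M). Neighbouring genes, such as those of a Hox cluster, share peaks and were counted singly, so these p-values can be too small. Counting neighbours as 1 locus was not run for the EPZ tests. Neuronal differentiation (5 of 32 in H3WT, 2 of 24 in K27M), signalling (5 of 39, 3 of 30) and imprinted genes (3 of 12, 0 of 9) were not separated from other marked genes (adjusted exact p of 0.125, 0.287 and 0.106 in H3WT and of 1, 1 and 0.913 in K27M). No marked member of the remaining 7 lists that had one kept a peak in both EPZ libraries of either genotype. With replicate 2 alone, 6 lists stood above other marked genes in H3WT. Whether lists differed between genotypes was not tested.

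Suz12 had more called peaks in the K27M library than in the H3WT library, at unknown read depth. It had 631 peaks over 2.05 Mb in H3WT and 1252 over 3.96 Mb in K27M, ratios of 1.98 in number and 1.94 in length, with 1 library each and therefore no test. Of the H3WT peaks, 74.3% (exact 95% interval 70.7 to 77.7%) were overlapped by a K27M peak, against 0.354% at random, and 47.7% had a K27M peak centre within 1 kb of their own. Of the K27M peaks 39.0% were overlapped by an H3WT peak. Genes with a Suz12 peak at an end numbered 369 in H3WT and 586 in K27M. Both genotypes shared 279, among them Hoxa10 (23.3 and 28.7 kb in H3WT and K27M), Hoxd10 (28.8 and 21.9 kb) and the homeobox gene Uncx (18.7 and 23.7 kb). The 307 genes with a peak in K27M alone included Arid3a, an AT-rich DNA-binding factor on chromosome 10 from 79927043 to 79955018 (0 kb in H3WT, 33.0 kb in K27M), Hoxa3 (0 and 28.1 kb), Hoxa6 (0 and 23.8 kb), Hoxa5 (0 and 22.8 kb) and the head patterning gene Otx2 on chromosome 14 from 48656781 to 48667644 (0 and 18.8 kb). Cdkn2a was also among them, at 0 and 11.9 kb. On chromosome 10 from 75000001 to 130497379, where Arid3a lies, were 27 of the 307 K27M-only genes and 0 of the 90 H3WT-only genes. Of the 307 genes, 297 carried H3K27me3 in both H3WT libraries and 261 were retained. The 90 genes with a peak in H3WT alone were led by Tfap2a (20.8 and 6.98 kb), Pax3, both regulators of neural crest (12.8 and 1.58 kb), and Msx2 (10.3 and 0 kb). By list, K27M-only and H3WT-only Suz12 genes numbered 5 and 1 for Hox clusters and 12 and 6 for other homeobox genes. They numbered 6 and 1 for mesoderm and endoderm factors, 7 and 2 for neuronal differentiation, and 11 and 2 for signalling. The counts were 0 and 2 for imprinted genes, 0 and 1 for neural stem and glial progenitors, 2 and 0 for cell cycle inhibitors, 2 and 1 for Polycomb and H3K27 enzymes, and 1 and 0 for PDGF and receptor tyrosine kinase genes. The remaining 4 lists had 0 in each.

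Ring1b had nearly equal numbers of peaks in the 2 genotypes, 1754 over 5.17 Mb in H3WT and 1808 over 7.54 Mb in K27M, ratios of 1.03 in number and 1.46 in length, again with 1 library each. Of the H3WT peaks 78.0% (76.0 to 79.9%) were overlapped by a K27M peak, against 0.555% at random. A Ring1b peak lay at an end of 1040 genes in H3WT and of 1219 in K27M. Both genotypes shared 823. The 396 genes found in K27M alone included Hoxa2 (2.30 kb in H3WT and 21.1 kb in K27M), Prss16, a thymic protease (3.92 and 19.5 kb), and Tbr1, a cortical neuron factor (4.43 and 17.2 kb). Cdkn2a had Ring1b in both genotypes, at 11.3 and 28.7 kb. The 217 genes in H3WT alone were led by the adjoining genes Dlg2 and Tmem126b (5.09 and 0 kb for each), followed by Acp1 (4.23 and 2.24 kb) and the protocadherin gene Pcdh10 (4.0 and 0 kb). On chromosome 10 from 75000001 to 130497379 lay 67 of the 396 K27M-only genes and 1 of the 217 H3WT-only genes.

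Suz12 and Ring1b peaks were more frequent at H3K27me3 peaks overlapped in K27M than at the others. In replicate 1, 19.5% of H3WT H3K27me3 peaks overlapped by a K27M peak also held an H3WT Suz12 peak and 30.4% a Ring1b peak, against 0.262% and 1.60% of the peaks that were not overlapped. In replicate 2, with more peaks, the shares were 3.21% and 6.0% against 0.00839% and 0.168%. Random placement gave means of at most 0.942% in these 8 comparisons, and all 4 shares of overlapped peaks lay above theirs. The peaks that were not overlapped differed by replicate. In replicate 1 their Ring1b share lay above the highest random share of 0.524%, and their Suz12 share lay within the highest of 0.297%. In replicate 2 both shares lay below the random means of 0.116% for Suz12 and 0.314% for Ring1b. Nearly all Suz12 peaks were overlapped by at least 1 bp by H3K27me3 peaks of the same genotype, 99.8% and 100% for the 2 H3WT replicates and 92.9% and 99.6% for the K27M ones. Of Ring1b peaks, 62.0% and 68.6% were overlapped in H3WT and 51.8% and 60.1% in K27M. A Ring1b peak of the same genotype overlapped 78.0% of Suz12 peaks in H3WT and 71.3% in K27M.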

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

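Peaks of at least 3 kb, the within-genotype EPZ tests, whole gene intervals, the EPZ gene lists, and autosomes only for gene classes and peak overlap were chosen after the results had been seen. Of 184 alternative values of 22 main results, 153 kept their direction and side of the threshold or moved by less than a set limit. Of the others, 0 reversed, 6 lost their p and 25 moved further. Peaks of at least 1 kb removed 0 peaks and tested nothing, so any of the 153 from that setting were unchanged by construction. Differences between genotypes within a treatment had too few relabellings to pass the threshold in any setting, so keeping their side was no test either. The 153 therefore do not measure how robust the results are. The CpG comparison and its alternatives were not run.

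The 6 lost p-values belong to the EPZ effect and follow from fewer relabellings. Without a replicate, covered length differed by -5.87 to -3.91 and peak number by -6.76 to -4.57 (log2, exact p = 0.333, the smallest possible). Replicate numbers share only a number: no label calls them a batch, and the 2 pairs are too few to tell, although replicate differences correlated between genotypes across 9358 genes (r = 0.545, genes not being independent). With the replicate block, EPZ gave -4.89 for length and -5.66 for number (exact p = 0.125, the smallest possible), K27M minus H3WT -1.71 and -2.12 (exact p = 0.5, the smallest possible, reached because both pairs went the same way), and the interaction 1.20 (p = 0.375).

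The retained share was 35.5% with 5 kb windows, 47.7% when marked in either replicate, and 41.2 to 47.8% without a replicate. Lost genes numbered 691, 2602 and 1364 to 2586 in these settings and 209 with peaks of at least 3 kb; gained genes numbered 1, 27 and 23 to 28. Lists kept under EPZ in H3WT were 6 when marked in either replicate and 3 to 6 without a replicate. Over all alternatives, 5 to 9 lists were called as marked in H3WT and 4 to 6 as retained. Counting neighbours as 1 locus called 9 lists in H3WT, where 4 of them (neural stem and glial progenitor, Polycomb, mesenchymal and housekeeping) stood below other loci. The other genes could chain into larger loci, which are marked more often, so these 4 lower calls can follow from locus size. H3WT peaks overlapped in K27M were 17.4% on average, 41.0% against the union of both K27M libraries and 25.6% with peaks of at least 3 kb. The Suz12 ratio was 2.48 without peaks touching regions in all EPZ libraries and 1.74 with peaks of at least 3 kb, and its overlap 62.5% and 66.4%, or 47.7% by centres within 1 kb. For Ring1b the ratio was 1.22 with peaks of at least 3 kb, and the overlap 73.2%, 93.1% and 55.4% in the same order. The cause was not tested. Of 476 alternative values for 119 named genes, 30 moved by over 1 SD. Unknown depth limits every count of peaks.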

Other observations

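Every test in this part was chosen, or for gene density split by factor, after its result had been seen, and every pattern was found in these data.

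Few genes had more H3K27me3 cover in both K27M libraries than in both H3WT libraries. Of 9358 genes with any H3K27me3 peak within 10 kb of an end in DMSO, 29 (0.310%) had both K27M libraries above both H3WT libraries and 2261 (24.2%) had both below. Exchangeable libraries would give 16.7% in each direction, but replicate 2 covered more in both genotypes, so that share does not apply here. Of the measured members of the fixed lists, 3 of 39 Hox genes lay above and 0 below, against 6 and 14 of 71 other homeobox genes and 3 and 10 of 43 mesoderm and endoderm factors. Covered length is capped by its windows. A gene at the cap in all 4 DMSO libraries, such as Hoxb3 at 40 kb, can lie neither above nor below, which limits the Hox counts. The counts were 0 and 12 of 40 for neuronal differentiation, 0 and 21 of 49 for signalling, 0 and 8 of 23 for germline genes and 0 and 7 of 14 for imprinted genes. They were 1 and 0 of 17 for Polycomb and H3K27 enzymes, 1 and 5 of 15 for neural stem and glial progenitors and 1 and 3 of 12 for PDGF and receptor tyrosine kinase genes. In the other 4 lists 0 lay above and 1 to 4 below, and no enrichment was tested. The 29, named here after their values were seen, included the neighbours Hoxa2 and Hoxa3 and the adjoining cerebellar patterning genes Zic1 (15.4 ± 14.3 kb in H3WT, 26.9 ± 1.19 kb in K27M, SD, n = 2) and Zic4 (30.9 ± 12.2 kb, 39.98 ± 0.0325 kb). They also included the T-box pair Tbx2 (14.6 ± 2.09 kb, 18.4 ± 1.49 kb) and Tbx4 (8.77 ± 2.94 kb, 15.9 ± 3.37 kb), Irx5 (12.9 ± 4.96 kb, 23.4 ± 0.438 kb), and the PRC1 gene Bmi1 (2.28 ± 3.22 kb, 9.32 ± 4.67 kb) with its neighbours Gm46725 and Spag6. Pdgfra and Gsx2, both on chromosome 5 (75151322 to 75198206 and 75075601 to 75077893), were also among them, as were Sec31b, Camkmt, Bcas3, Cir1, Aatf and Zgrf1, which are in none of the fixed lists. Regions of at least 1 kb under peaks in both K27M libraries and in neither H3WT library numbered 38 and covered 0.0807 Mb, and 22 of them bordered an H3WT peak. By comparison, 11.8 Mb lay under peaks in both H3WT libraries and in neither K27M library.

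The 104 genes with H3K27me3 in all 4 EPZ libraries mostly had Suz12 and Ring1b peaks in H3WT cells in DMSO. A Suz12 peak lay at 100 of them (96.2%) and a Ring1b peak at 102 (98.1%), against 245 (28.8%) and 327 (38.4%) of the other 852 retained genes (Fisher's exact test, p = 1.64e-43 and 3.66e-36, with neighbouring genes counted singly).

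Distal chromosome 10 (75000001 to 130497379, 641 genes) held 48 Suz12 peaks found in K27M alone against 1 in H3WT alone, and 86 against 1 for Ring1b, which with 1 added to each count are log2 ratios of 4.61 and 5.44, against medians of 2.0 and 0.70 in 270 other autosomal windows of that length and highest values of 5.21 and 2.15. For Ring1b the ratio lay 3.29 above the highest of the 38 windows with at least as many genes (39 against 8 peaks). The exact 95% intervals of the K27M-only share were 69.2 to 92.4% there and 93.8 to 99.97% on distal chromosome 10. For Suz12 the margin was 0.57 (32 against 1 peaks) and the intervals overlap. The segment was picked from these same peaks, so the margins do not exclude gene density for either factor. More copies of this segment in the K27M cells may account for the K27M-only peaks. The ratio of H3K27me3 length, K27M over H3WT, was above that of 88.5% and 78.1% of the other windows in replicates 1 and 2. These shares are below the 95% set for a gain and above the median. More copies of the whole of chromosome 10 stay open too: the log2 ratio on the rest of the chromosome was -0.50 for Ring1b (11 against 16 peaks) and 2.70 for Suz12 (12 against 1), but the boundary was set from these same peaks, so the contrast excludes nothing. A difference in binding between genotypes cannot be told apart from copy number here, because each factor has 1 library per genotype and input or IgG reads were not used here.

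Chromosome X took 30.9% and 36.4% of the covered length in replicate 2 of H3WT and K27M in DMSO, against 10.0% and 3.54% in replicate 1. The length on X was 15.4-fold and 50.1-fold larger in replicate 2, and that on single autosomes 3.3-fold to 5.24-fold in H3WT and 2.77-fold to 6.09-fold in K27M. In replicate 2, 84.4% and 43.7% of 1 Mb bins of X were at least 10% covered. No explanation was tested, and depth, caller settings and differences between the cultures stay open.

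Developmental lists lay under wide H3WT peaks, so wide H3K27me3 domains in H3WT were a candidate explanation for their retention in K27M. Each list gene was set against up to 20 other marked genes, the next in width, whose widest H3WT peak at a gene end was at least as wide (10000 draws, genes taken as independent although neighbours share peaks). In the lists called for retention other than the Hox clusters, 141 of the 165 genes that could be matched (85.5%, 5 could not) were retained. The draws gave a mean of 114 (68.9%, central 95% 104 to 123, permutation p = 0.0001, the smallest these draws can give). For these lists together, more genes were retained than in the draws. The lists were picked for high retention in these same data, and their members were left out of the draws. Part of this excess is therefore built in. Genes that share peaks were drawn as independent, so the central range may be too narrow and width is not excluded. By list, the permutation p was 0.0001 for other homeobox genes and for signalling, 0.012 for mesoderm and endoderm factors and 0.172 for neuronal differentiation (23 of 32 against a mean of 20.3), where width stays open. It stays open for the Hox clusters too, since 34 of their 37 marked genes had fewer than 5 marked genes as wide, and peak height, CpG content and Suz12 occupancy may contribute and were not tested in this way.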
